A study of Mus musculus with 10 samples.

How the data were processed

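All samples were mouse cochlear duct epithelium at embryonic day 13.5, freed with dispase and collagenase. ATAC-seq was made from unsorted tissue (whole epithelia in the protocol, whole organ in the titles) of wildtype (3 libraries) and SoxC double knockout embryos (2 libraries). Sox4 CUT&RUN was made from FACS-sorted p27kip1-GFP positive progenitors (3 replicates, called ChIP in the titles). Single-cell RNA libraries (10x Genomics, 3' version 2 chemistry) came from a wildtype p27GFP strain and from Pax2cre SoxC fl/fl embryos, with 1 library each. Groups were taken from the titles and genotype labels, and no sample was left out.

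The deposited ATAC and Sox4 files were MACS2 peak lists with 1 line per peak. The fold enrichment of a peak over the local background of its own library was deposited as a ratio, and its significance was deposited as -log10 p and -log10 q, with the summit given as an offset in bp. The submitters' processing notes named STAR, MACS2, deepTools and, for Sox4, UMI-tools, without versions, and the builds mm10 and GRCm38. The wildtype notes differed between replicates, with MACS2 and deepTools alone for replicate 2. The names of the knockout lists stated a p threshold of 0.01 and a cap on the number of peaks, which the wildtype names did not. The lowest -log10 p was 2.00 in all 3 wildtype lists and in knockout replicate 2 and 3.98 in knockout replicate 1, all below the peaks kept for the comparisons. The wildtype lists held no peaks on chromosomes X or Y. A further list of Sox4 replicate 1, whose peak names carried another library tag, was used only as an alternative, on its own in place of the Sox4 sites. The single-cell files held UMI counts per row and cell barcode, as deposited by the authors with no normalization (Cell Ranger 2.1.1 per the processing notes). They gave no gene names.

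Overlapping peaks within a library were merged, keeping the strongest summit, and ranked by -log10 p. The 50000 strongest autosomal ATAC peaks and 20000 strongest Sox4 peaks per library were reduced to windows of 250 bp on each side of the summit, and overlapping windows were merged into regions across libraries. At rank 50000 the -log10 p was 19.0, 10.5 and 8.75 in the wildtype and 104 and 50.5 in the knockout libraries. Wildtype-only regions were in all 3 wildtype and no knockout library, knockout-only regions in both knockout and no wildtype library, and shared regions in all 5. A Sox4 site had windows in at least 2 of 3 replicates. Genes were the 20665 autosomal coding genes of a RefSeq table of the mm10 build, and listed genes were matched by symbol or synonym, which placed every one not on X. The 10000 strongest peaks of each ATAC library lay within 1 kb of a gene end in 52.3% to 59.0% of cases, and in 5.32% to 7.78% after a shift of 10 kb, as a check of the build.

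Shares were given with exact binomial intervals and single-cell sums with exact Poisson intervals, both at 95% and for counting error only. Overlaps of classes with Sox4 sites, gene ends and 18 gene lists were tested with two-sided Fisher exact tests over regions, with Benjamini-Hochberg adjustment over the lists. A region was assigned to the nearest coding gene within 100 kb. The lists were SoxC family, prosensory domain, hair cell, supporting cell, medial floor, roof and lateral wall, spiral ganglion neuron, otic mesenchyme, glia and melanocyte, blood with endothelium and macrophage, Notch, Wnt, Fgf, BMP and TGF-beta, Hippo and TEAD, cell cycle, housekeeping and epithelium. Sites were also placed at random 100 times on their own chromosomes, and gene lists were drawn 10000 times matched on wildtype-only and knockout-only regions per gene. The similarity of ATAC libraries was tested with an exact permutation over 10 splits. Single cells with under 1000 UMIs or under 500 rows with a UMI were left out (30 wildtype and 309 knockout), doublets were not searched for or removed, UMIs were summed per library as CPM, and rows with at least 10 CPM in 1 library and a ratio of at least 2 were counted without a test.

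The main tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named 10 genes (Sox4, Sox11, Sox2, Atoh1, Pou4f3, Gfi1, Jag1, Prox1, Isl1 and Lgr5) and the 8 regions per class with the best worst rank among those absent from the full lists of the other genotype. It also named the 8 Sox4 sites with the best worst rank over all 3 replicates, and up to 4 genes per class in lists that passed and in the prosensory, hair cell and supporting cell lists. For the single-cell tables it allowed 2 rows each way. Not every gene that the rule names is reported here. The plan was changed where the files required it. Chromosome X was left out because the wildtype lists held none of it. The gene table gave no strand, so distances to either gene end took the place of distances to transcription starts. No genome sequence was used, so the planned tests of 22 motifs were not run.

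Alternatives covered 25000, 100000 or all peaks, full peak extents, the full lists of the other genotype, other distances, Sox4 sites in all 3 replicates, 10000 or all Sox4 peaks, the further list of replicate 1, each replicate left out, strata of rank, and other cell filters, CPM limits and scalings. Added after the data had been seen were chromosome X, regions away from gene ends, strata of gene density and of wildtype rank with gene ends, ratios relative to the median and the lists without Cdkn1b. On simulated peak lists, all 2000 planted regions of each class and all 940 planted Sox4 sites were found. Planted regions stood in every library of their genotype and planted sites in all 3 replicates, with no cut in rank. Full recovery was thus fixed by construction and does not cover missing peaks, unequal depth or the cut in rank. With class labels shuffled over single regions, 4 of 900 list tests without an effect passed, and a planted list passed in 48 of 50 runs. Such shuffling removes the grouping of regions by gene and by gene density, so these runs do not cover either. In simulated single-cell tables, which held counting error only, 200 of 200 rows changed 3-fold were recovered, with 0 of 8108 others. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.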

Results

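The series followed the cochlear duct epithelium of mouse embryos at E13.5, when the precursors of the organ of Corti leave the cell cycle. Wildtype tissue was compared with SoxC double knockout tissue. SoxC transcription factors bind DNA through an HMG box, and a SoxC double knockout usually means the loss of Sox4 and Sox11, although the labels do not name the deleted genes. Open chromatin was profiled by ATAC-seq in 3 wildtype and 2 SoxC double knockout libraries. Sox4 binding was mapped by CUT&RUN in 3 replicates of sorted p27kip1-GFP positive wildtype progenitors. Single-cell RNA was counted in 1 wildtype and 1 SoxC knockout library, from different strains. The wildtype ATAC lists held 196536, 166874 and 196345 peaks and the knockout lists 299829 and 266873. The Sox4 lists of replicates 1 to 3 held 163020, 73346 and 39325 peaks. No read totals or counts per peak stood in the peak lists, so sequencing depth was unknown and chromatin was compared by the presence of peaks at equal rank. Coordinates are 1-based positions of the mm10 build.

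The first comparison asked which chromatin was among the most open in one genotype and not in the other. The 50000 strongest autosomal peaks of each ATAC library were used, reduced to 501-bp windows around their summits. A region near Sox11 on chromosome 12 (27359583 to 27360214, 16865 bp from the gene) ranked 14834, 10371 and 13694 in the wildtype libraries and 78144 and 87945 in the knockout libraries. Beside Isl1, which encodes a LIM-homeodomain factor of the prosensory domain and of neurons, a region 439 bp from the gene (chromosome 13, 116297297 to 116297831) ranked 22631, 13959 and 13177 in wildtype and 72949 and 68433 in knockout. At Atoh1, the bHLH factor required for hair cell formation, a region over the lower-coordinate end of the gene (chromosome 6, 64728743 to 64729275) ranked 34789, 26341 and 32186 in wildtype. It had no peak in knockout replicate 1 and rank 58447 in knockout replicate 2, where its -log10 p of 38.1 was above the 31.8, 23.1 and 14.2 of the wildtype libraries.

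Over the genome, 76102 regions were open in at least 1 library, and 28321 of them (37.2%) in all 5. In all 3 wildtype and neither knockout library 4998 regions were found (wildtype-only), and 6059 in both knockout and no wildtype library (knockout-only). Of the wildtype-only regions, 4596 had a peak in both full knockout lists, so their class rested on the cut in rank or on the summit windows, and 165 (3.30%) had none in either. Ranks were not scaled to list length, and the full lists held 165038, 145099 and 173032 merged autosomal peaks in wildtype and 208902 and 192810 in knockout. Of the knockout-only regions, 2276 had a peak in all 3 full wildtype lists and 441 (7.28%) in none, so most lacked a peak in at least 1 wildtype library. Without knockout replicate 2, which leaves 1 knockout library, 9340 regions were knockout-only. The Jaccard index, the share of regions in either library that both held, was 0.706 ± 0.063 (SD, n = 4 pairs) within genotypes and 0.556 ± 0.039 (SD, n = 6 pairs) between them. The lowest index within a genotype was 0.654 and the highest between genotypes 0.610. The genotype split had the largest difference in mean Jaccard index, 0.150, of the 10 splits of the 5 libraries (exact permutation p = 0.1, one-sided, the smallest this design allows). With all deposited peaks the difference was 0.0757 (exact permutation p = 0.2), so the genotype split was not the only one so large. At rank 50000 the -log10 p was higher in both knockout lists (104 and 50.5) than in the 3 wildtype lists (lowest 8.75), so peak significance differed with genotype. The lists also differed with genotype in the stated calling settings and in the presence of chromosome X. Neither the permutation nor the region counts can therefore tell genotype apart from the processing of the lists.

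**Figure D1:**
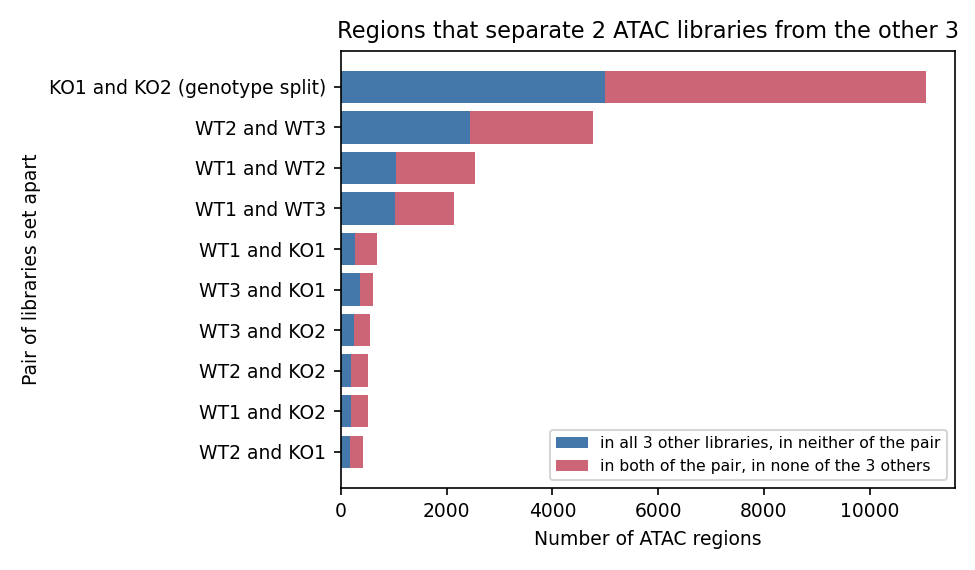
Number of ATAC regions (x axis) that separate each pair of libraries (y axis) from the other 3, with blue for regions in the other 3 libraries and neither of the pair, and red for regions in both of the pair and none of the other 3. Setting the 2 knockout libraries apart gave 11057 regions, and the next highest pair, wildtype replicates 2 and 3, gave 4770.

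Among regions with no peak at all in the full lists of the other genotype, the strongest wildtype-only ones lay in or near Ryr2, Sox12, Tmem161b, Chodl, Aadacl4fm1, Limch1, 4930583I09Rik and Fam155a. The Sox12 region (chromosome 2, 152396175 to 152396682) lay inside the gene, which encodes a further SoxC factor, and its worst rank in the wildtype libraries was 11299. The Ryr2 region (chromosome 13, 11348444 to 11348959) lay 204140 bp from the gene of a ryanodine receptor, and its worst rank was 9601. The strongest knockout-only regions lay in or near Hjurp, Gm40369, Crebzf, Taco1, Ttyh3, Bbs2, Brat1 and Cdk20. The region inside Hjurp, which encodes a chaperone of the centromeric histone (chromosome 1, 88277357 to 88277868), was the strongest peak of both knockout libraries and had no peak in any wildtype list. Peaks were not filtered here for regions of artefact signal, and whether these regions are such was not tested. The regions beside Gm40369 and inside Taco1 and Brat1 also overlapped Sox4 sites from wildtype cells.

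Around 10 genes of SoxC function and sensory differentiation fixed before the data were examined, 9 wildtype-only and 2 knockout-only regions lay within 100 kb. Sox4 had 2 wildtype-only and 1 knockout-only region, and Atoh1 had 2 wildtype-only regions. Sox11, Sox2, Jag1, Isl1 and Lgr5 had 1 wildtype-only region each. Pou4f3, a factor of hair cell maturation, had 1 knockout-only region, and Gfi1 and Prox1 had neither. Each of these wildtype-only regions also overlapped a peak in both full knockout lists, except the region over the end of Atoh1. By -log10 p the order often differed from that by rank. At the wildtype-only regions of Sox4, Sox2, Atoh1, Jag1 and Lgr5, a knockout library had a higher value than every wildtype library. The Sox2 region had 34.6, 12.2 and 12.2 in wildtype and 85.1 and 48.5 in knockout. The Sox4 region at 28876675 had 35.9, 20.9 and 12.5 against 48.4 and 28.4. Only the Sox11 and Isl1 regions lacked this. The Sox11 region had 79.4, 55.8 and 33.6 against 45.0 and 16.8. The Isl1 region had 52.6, 43.6 and 34.7 against 52.0 and 27.8. The other Atoh1 region (64734301 to 64735005, 3056 bp from the gene) ranked 44796, 46663 and 28405 in wildtype and 60203 in knockout replicate 2. In knockout replicate 1 it was overlapped by a 1475-bp peak at rank 951 whose own summit window, 2005 bp from the gene, was found in no other library.

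**Figure D2:**
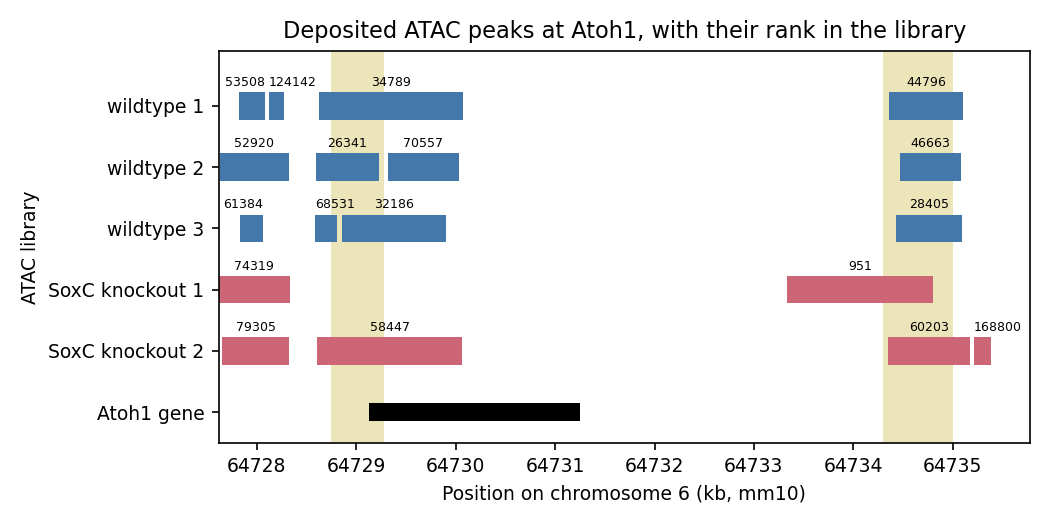
Deposited ATAC peaks around Atoh1 in each of the 5 libraries (y axis) by position on chromosome 6 in kb (x axis), with the rank of each peak in its library printed above it, wildtype in blue, knockout in red and the gene in black. The shaded regions are the wildtype-only regions, and the peak at rank 951 stands in knockout replicate 1 alone.

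The second question was near which groups of genes the genotype-specific regions lay. Medial floor genes, which mark the greater epithelial ridge beside the sensory domain, were nearest to 19 wildtype-only and 6 knockout-only regions (odds ratio 4.64, 95% interval 1.85 to 11.6, Fisher exact adjusted p = 0.00705 over 18 lists). The call ended with random gene lists matched on regions per gene (adjusted p = 0.365), in strata of gene density (odds ratio 3.97, adjusted p = 0.563), with genes within 10 kb (5.64, 0.0705), with 25000 peaks (7.30, 0.0601) and with 100000 peaks (2.18, 0.130). Lmo3 had 6 wildtype-only regions and no knockout-only one. Otogl, the gene of a tectorial membrane protein, had 4 and 1, and Fgf10 and Fst, which encode a growth factor and an activin antagonist, had 2 and 0 each. Otoa had 2 knockout-only regions, and Ntn1 and Otog had 1 each, with no wildtype-only region near these 3. Of the 20 medial floor genes, 7 had wildtype-only regions alone, 4 knockout-only regions alone, 1 both and 8 neither.

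Prosensory genes were nearest to 24 wildtype-only and 13 knockout-only regions (odds ratio 2.71, 95% interval 1.38 to 5.32, Fisher exact adjusted p = 0.0342). Eya1, a transcriptional coactivator gene, had 3 wildtype-only regions, and Gata3 and Lin28b had 2 each, all with no knockout-only region. Mycn had 2 and 1. Notch1 and Pax2 had 3 knockout-only regions each and no wildtype-only one, Lfng, whose product modifies Notch receptors, had 1 wildtype-only and 2 knockout-only regions, and Hmga2 had 1 of each. Of the 25 prosensory genes, 13 had wildtype-only regions alone, 4 knockout-only regions alone, 4 both and 4 neither, and 16 also stood in another list. The prosensory call ended with random gene lists matched on regions per gene (adjusted p = 0.335), in strata of gene density (odds ratio 2.01, adjusted p = 0.753), with genes within 10 kb (3.30, 0.0705) and with 25000 peaks (2.15, 0.432). It also ended without wildtype replicate 1 or 3 (odds ratio 2.00 and 2.07, adjusted p = 0.181 and 0.168). Without knockout replicate 1 or 2, which leaves 1 knockout library, the odds ratio was 2.09 and 1.98. With the 100000 strongest peaks it was 0.888 (adjusted p = 0.919).

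**Figure D3:**
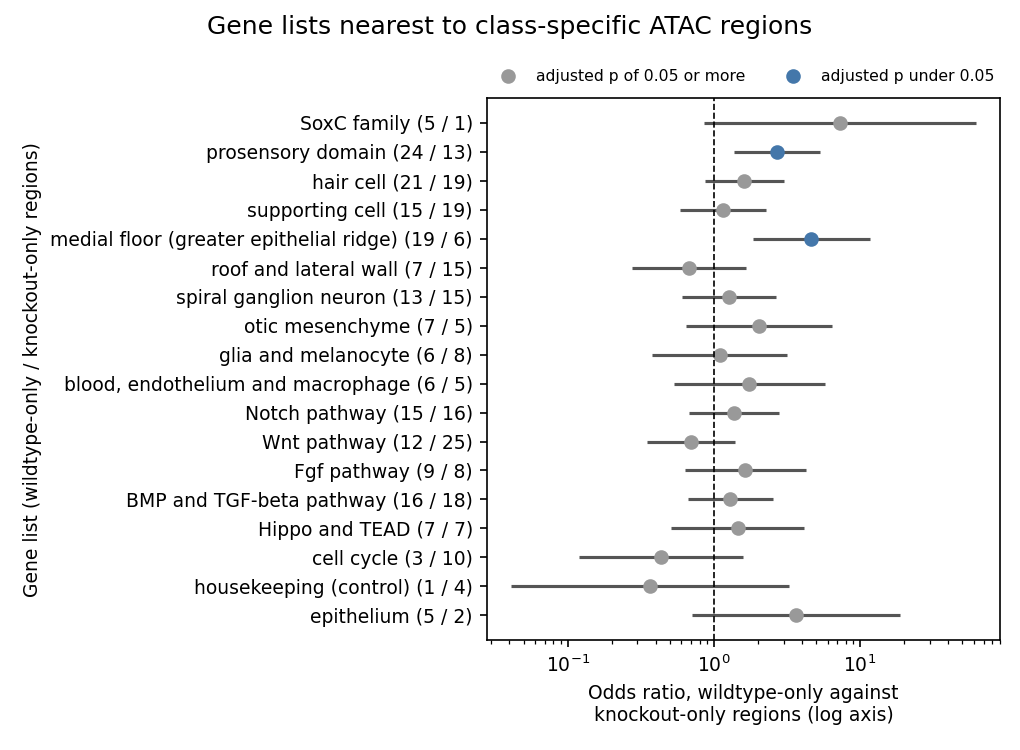
Odds ratio (points, log x axis) with 95% interval (lines) of wildtype-only against knockout-only regions for each of the 18 gene lists (y axis), with the number of regions of each class in parentheses and the dashed line at 1. The prosensory and medial floor lists, in blue, had an adjusted p under 0.05.

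Hair cell genes were nearest to 21 wildtype-only and 19 knockout-only regions and did not pass (odds ratio 1.62, adjusted p = 0.528). Within this list Pcdh15, the gene of a tip link protein, had 6 wildtype-only regions, Xirp2 3, and Atoh1 and Slc26a5, which encodes prestin, 2 each, with no knockout-only region. Myo7a, the gene of a stereocilia myosin, had 4 knockout-only regions and Tmc1 2, with no wildtype-only one, while Kcna10 had 1 wildtype-only and 2 knockout-only regions. Supporting cell genes were nearest to 15 and 19 regions (odds ratio 1.15, adjusted p = 0.771). Nrcam had 3 and 2 regions, Bace2, Cdkn1b and Gjb6 had 1 and 0 each, Etv4, Heyl and Id4 had 0 and 2 each, and Lfng had 1 and 2. The SoxC genes Sox4, Sox11 and Sox12 together were nearest to 5 wildtype-only regions and 1 knockout-only region (odds ratio 7.31, adjusted p = 0.264).

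None of the other 13 lists passed with 50000 peaks. The odds ratio was 0.681 for roof and lateral wall genes (7 wildtype-only and 15 knockout-only regions), 1.27 for spiral ganglion neurons (13 and 15), 2.05 for otic mesenchyme (7 and 5) and 1.10 for glia and melanocytes (6 and 8). It was 1.75 for blood, endothelium and macrophage genes (6 and 5) and 3.65 for epithelium (5 and 2). Among pathways it was 1.37 for Notch (15 and 16), 0.700 for Wnt (12 and 25), 1.64 for Fgf (9 and 8), 1.30 for BMP and TGF-beta (16 and 18) and 1.46 for Hippo and TEAD (7 and 7). It was 0.438 for cell cycle genes (3 and 10) and 0.365 for housekeeping genes (1 and 4). Adjusted p was 0.528 or more in these 13 lists. Spiral ganglion neuron genes passed with 100000 peaks (odds ratio 2.68, adjusted p = 0.0456) and with all peaks (2.93, 0.0157), and roof and lateral wall genes with all peaks (0.196, 0.0329). In all, 3895 wildtype-only and 5688 knockout-only regions had a coding gene within 100 kb, so 40.6% were wildtype-only.

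The share of regions within 1 kb of either end of a coding gene was 10.1% (506 of 4998, 95% exact interval 9.30 to 11.0) in the wildtype-only class, 8.14% (493 of 6059, 7.46 to 8.85) in the knockout-only class and 34.6% in shared regions. The odds ratio of wildtype-only against knockout-only regions was 1.27 (1.12 to 1.45, Fisher exact p = 0.000316). It was under 1 with a limit of 2000 bp (0.969, Fisher exact p = 0.580), with full peak extents (0.842, p = 0.0242) and with the full lists of the other genotype (0.249, p = 0.00428), and without wildtype replicate 1 it was 1.06 (Fisher exact p = 0.316), while with all deposited peaks it was 2.63 (Fisher exact p = 9.27e-55). Wildtype-only regions had on average 7.04 coding genes within 500 kb, knockout-only regions 15.9 and shared regions 13.6.

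The third question was where Sox4 bound in wildtype progenitors. The 20000 strongest autosomal peaks of each replicate gave 1701 sites in at least 2 of 3 replicates and 385 in all 3. Random placement on the same chromosomes gave means of 499 (range 436 to 560 over 100 draws) and 2.01 (0 to 6). With replicate 1, 2 or 3 left out, 901, 818 and 733 sites were shared by the remaining replicates. Sites inside Jag1, a Notch ligand gene (chromosome 2, 137107251 to 137107995), and 65354 bp from Lgr5, an R-spondin receptor gene (chromosome 10, 115384330 to 115384960), were found in all 3 replicates. Sites 11098 bp from Pou4f3, inside Prox1 and inside Lgr5 were found in 2. No site lay within 100 kb of Sox4, Sox11, Sox2, Atoh1, Gfi1 or Isl1. Single replicates had peaks inside Sox4 (rank 104 in replicate 1 and 336 in replicate 3) and Sox11 (1995 in replicate 1 and 8844 in replicate 2), whose windows did not overlap between replicates. Replicates shared few of their peaks: 5.96%, 6.34% and 6.92% of the windows of replicates 1 to 3 were also in another replicate. No control antibody library was used here.

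The 8 strongest sites of the 3 replicates lay nearest to Tnc, Alkbh8, Kcnh5, Zfp524, Lars2 and Hnrnpa1, with 3 of them between 3001970 and 3033692 on chromosome 9, at 301539 to 332673 bp from Alkbh8. The strongest (chromosome 4, 64497669 to 64498269) lay 450654 bp from Tnc, the gene of an extracellular matrix protein, and was the top peak of all 3 replicates. Of these 8, the sites inside Zfp524 (chromosome 7, 5014713 to 5015316) and Hnrnpa1 (chromosome 15, 103239880 to 103240425) lay in chromatin open in wildtype. The site inside Lars2 lay in chromatin open in the knockout libraries alone, and the remaining 5 in neither. Artefact signal at these sites was neither filtered out nor tested for.

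Of the 1701 sites, 1020 (60.0%, 95% exact interval 57.6 to 62.3) lay in regions open in all 3 wildtype ATAC libraries, against a mean of 1.83% (range 1.00 to 2.65) for randomly placed sites (permutation p = 0.0099, the smallest that 100 draws can give). Placement was uniform along each chromosome and no control antibody library was used. The comparison thus cannot tell Sox4 binding from signal at any open chromatin. The share was 90.4% (87.0 to 93.1) for sites found in all 3 replicates. Among all kept Sox4 windows of a replicate, shared or not, it was 8.655% in replicate 1, 9.225% in replicate 2 and 10.875% in replicate 3. The 60.0% and 90.4% thus describe sites shared between replicates and not the Sox4 windows as a whole. In the knockout libraries, 58.0% of the sites lay in regions open in both. Within 1 kb of a gene end lay 36.3% of the sites, against 3.17% of randomly placed ones.

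Sox4 sites were found in 57 of 4998 wildtype-only regions (1.14%, 95% exact interval 0.865 to 1.48), in 14 of 6059 knockout-only regions (0.231%, 0.126 to 0.387) and in 963 of 28321 shared regions (3.40%, 3.19 to 3.62). Wildtype-only regions with a site lay, among others, 418 bp from Fzd7, which encodes a Wnt receptor, inside Ctnna2 and Sema4c, and 25018 bp from Yap1, the Hippo pathway effector. Knockout-only regions with a site lay inside Lars2, Brat1 and Taco1 and 13074 bp from Myh9. Examples other than Lars2, Brat1 and Taco1 were chosen after their values were seen. The odds ratio was 4.98 (2.77 to 8.95, Fisher exact p = 1.98e-09) for wildtype-only against knockout-only regions and 0.328 (0.250 to 0.429, Fisher exact p = 1.79e-21) for wildtype-only against shared regions. With the full lists of the other genotype searched, 0 of 165 wildtype-only and 8 of 441 knockout-only regions held a site (Fisher exact p = 0.115), and in deciles of the best rank the odds ratios were 1.91 and 1.83. The tests ran over regions, which are not replicates, and cover counting error only.

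**Figure D4:**
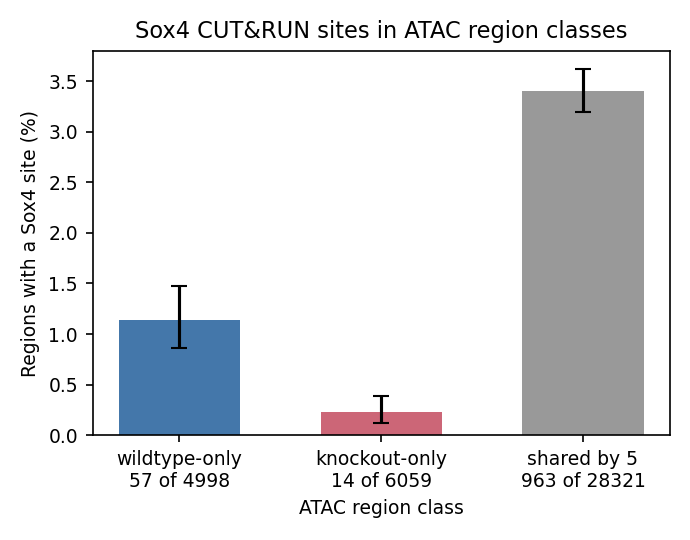
Percent of ATAC regions that overlap a Sox4 site (y axis, bars, with 95% exact binomial intervals) in each region class (x axis), with the counts under each bar. The share was 1.14% in wildtype-only, 0.231% in knockout-only and 3.40% in shared regions.

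Among regions open in wildtype, those nearest to supporting cell genes held Sox4 sites more often than the rest: 12 of 110 regions (10.9%) held a site, against 972 of 32136 (3.02%) of all wildtype open regions with a gene within 100 kb (odds ratio 3.96, 95% interval 2.17 to 7.24, Fisher exact adjusted p = 0.00229 over 18 lists). They lay near 9 genes. Cdkn1b had 3 such regions, Trpm3 2, and Cep41, Etv4, Etv5, Id4, Lgr5, Slc1a3 and Sox9 1 each, a list given after the values were seen. Cdkn1b encodes p27kip1, the cell cycle inhibitor whose reporter defined the sorted cells, and without it the odds ratio was 3.00 (1.51 to 5.96) and the list did not pass (adjusted p = 0.0867). The call also ended without Sox4 replicate 1 or 3 (odds ratio 2.52 and 3.19, adjusted p = 0.330 and 0.145). It ended too with sites found in all 3 replicates (2.61, 0.682) and with the 10000 strongest peaks (3.09, 0.0912), so the odds ratio stayed above 1 in these settings. The test ran over regions, so several regions of the same gene counted separately. Neither random gene lists matched on regions per gene nor strata of rank were run for the Sox4 lists.

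Prosensory genes had a site in 10 of 128 regions (7.81%, odds ratio 2.73, adjusted p = 0.0505), near genes that included Cdkn1b with 3, Id2 with 2, and Id3, Jag1, Lgr5 and Notch1 with 1 each. The prosensory list passed with genes within 10 kb (odds ratio 3.44, adjusted p = 0.0196), with all Sox4 peaks (2.34, 0.0260) and with the further list of replicate 1 (3.62, 0.00479), and without Cdkn1b the odds ratio was 1.93 (adjusted p = 0.355). Of its genes, 7 also stood in the supporting cell list. Hair cell genes had a site in 0 of 121 regions (adjusted p = 0.198), and passed as depleted with all Sox4 peaks (odds ratio 0.111, adjusted p = 0.0260). Regions near BMP and TGF-beta genes held a site in 8 of 119 cases (6.72%), near Notch genes in 6 of 105 (5.71%), near epithelium genes in 5 of 60 (8.33%), near Fgf genes in 3 of 73 (4.11%) and near housekeeping genes in 3 of 42 (7.14%). Cell cycle genes had 2 of 64, Hippo and TEAD genes 2 of 73, Wnt genes 2 of 107, medial floor genes 1 of 59, otic mesenchyme genes 1 of 52, blood, endothelium and macrophage genes 1 of 26 and SoxC genes 1 of 13. No region near roof and lateral wall genes (0 of 64), spiral ganglion neuron genes (0 of 63) or glia and melanocyte genes (0 of 29) held a site. Adjusted p was 0.157 or more for each list other than the supporting cell and prosensory ones, and epithelium genes passed without Sox4 replicate 2 (odds ratio 5.16, adjusted p = 0.0353).

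Around Cdkn1b (chromosome 6, 134920401 to 134925525) 6 Sox4 sites lay within 100 kb, and 15 of 20665 coding genes, this one included, had 6 or more. The sites at 134897810 to 134898746 and at 134951267 to 134951966 were found in all 3 replicates. The 3 Sox4 replicates had 8, 9 and 14 windows within 100 kb of this gene, against a median of 2 per coding gene, and the ATAC libraries had 15 to 17 windows against medians of 7 to 9. The cells of the Sox4 libraries carried a reporter of this gene, and an effect of the reporter on the signal here was not tested.

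The fourth comparison was of the single-cell libraries, whose tables gave UMI counts for 27998 rows without gene names, so neither genes nor cell types were named. After a filter of at least 1000 UMIs and 500 rows with a UMI, 7705 wildtype and 5858 knockout cells remained, with 99561364 and 86627458 UMIs. Doublets were not removed, and the highest totals per cell were 55283 and 56663 UMIs. The median UMIs per cell were 10430 and 12260.5 and the median rows with a UMI 3161 and 3083.5. After thinning each cell with at least 2000 UMIs to that number, the median numbers of rows were 1012 in wildtype and 893 in knockout cells. This left out 12 wildtype and 91 knockout cells with fewer UMIs.

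The expression profiles of the libraries correlated across 20472 rows, which are not independent replicates, with Spearman's rho of 0.959. Row 16166 had 1.51 CPM (UMIs of the row scaled to equal library totals) in wildtype and 296 in knockout cells (95% Poisson intervals 1.28 to 1.77 and 292 to 299), a 196-fold higher value, with a UMI in 1.26% and 29.0% of cells. The neighbouring row 16167 was 163-fold higher in the knockout library (3.31 and 541 CPM). Row 27846 was 349-fold lower there (217 CPM in wildtype and 0.623 in knockout, intervals 214 to 220 and 0.468 to 0.813), with a UMI in 29.6% and 0.563% of cells, and row 10139 was 70.5-fold lower (98.5 and 1.40 CPM). Without cell types, no background share of free RNA could be measured for these rows. Each genotype had 1 library from a different strain, so no test was made, and the intervals cover counting error only.

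Of 8675 rows with at least 10 CPM in 1 library, 346 were at least 2-fold higher and 757 at least 2-fold lower in the knockout library. The median log2 ratio of these rows was -0.30. Relative to that median, 573 rows were higher and 412 lower, and with TMM factors 511 were higher and 458 lower. The side with more rows thus turned with the scaling.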

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

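Both results below lie in data outside the comparisons, and the count on chromosome X was made only after the wildtype lists had been found to hold no X peaks. Of the 20000 strongest peaks in the further list of Sox4 replicate 1, 4.91% lay in regions open in all 3 wildtype ATAC libraries, against a mean of 1.60% and a highest value of 1.85% for randomly placed peaks. For the 20000 strongest peaks in the main list of replicate 1 the share was 8.655%. On chromosome X, where the wildtype ATAC lists held no peaks, 15 Sox4 sites were found in at least 2 of 3 replicates, and 8 of them overlapped peaks of both knockout lists. Neither result was explained or tested further.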

How the results depend on the processing

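Chosen after the data had been seen were the counts with chromosome X, the regions over 1 kb from gene ends, both strata by gene density, the strata by wildtype rank and gene end, the ratio relative to the median and the lists without Cdkn1b. No paired analysis was possible because the results come from the presence of peaks and from single libraries, not from a fit on samples. The motif alternatives were not run, and alternatives planned on transcription starts were run on gene ends. Of 147 alternatives of the main results, 87 kept direction and side of the threshold or a like value, and of 401 alternatives of single lists, 372 did. Among lists that passed in neither setting, the odds ratio crossed 1 in 30 of 209 alternatives of the region lists and in 32 of 148 of the Sox4 lists. Unless stated, the cause was not tested. Depth limits all region counts, since reads per library were unknown.

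Counts follow from how many peaks are kept or searched. With 25000 peaks 3021 wildtype-only and 3390 knockout-only regions were found, with 100000 peaks 6393 and 11806, and with all peaks 4233 and 30947, so only the knockout-only class grew with all peaks. With the full lists of the other genotype 165 and 441 remained. Leaving out each library gave 5930 to 7336 wildtype-only and 7083 to 9340 knockout-only regions, the highest without knockout replicate 2. Sox4 sites numbered 385 in all 3 replicates, 932 with 10000 peaks, 11804 with all peaks, 19999 with the further list of replicate 1 (used alone, so that every window counted) and 733 to 901 with each replicate left out, since both others had to hold a site. The share of sites in wildtype open chromatin was then 90.4%, 77.1%, 20.4%, 4.91% and 69.3% to 69.7%, and it was 55.3% with 25000 ATAC peaks and 62.9% with all of them.

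The odds ratio of Sox4 sites in wildtype-only against knockout-only regions was 0 with the full lists of the other genotype (0 and 8 regions with a site), 1.91 in deciles of the best rank, 2.03 with the further list of Sox4 replicate 1, 2.86 with full extents, 3.32 with all Sox4 peaks, 7.56 with 25000 ATAC peaks, 7.60 with all of them and 8.04 over 1 kb from gene ends. It was 4.39 to 7.30 with each library left out. Against shared regions it reversed to 1.83 in deciles of the best rank and to 1.46 in strata of wildtype rank and gene end, so the lower share of sites did not hold at equal rank, and was 0.247 to 0.366 with each library left out. The odds ratio near gene ends was 0.969 at 2000 bp, 0.842 with full extents, 0.249 with full lists, 1.44 with 25000 peaks, 1.53 with 100000, 2.63 with all peaks, and 1.06 to 1.71 with each library left out, the lowest without wildtype replicate 1.

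Near genotype-specific regions 2 lists passed. With random gene lists or strata of gene density 0 of the 18 lists passed, and with genes within 10 kb or 25000 peaks 0 of the 17 with a finite odds ratio. With full lists of the other genotype 0 of 7 such lists passed, and medial floor was not among the 7. With 100000 peaks 1 list passed, spiral ganglion neurons in place of the first 2, and with all peaks 3 passed (medial floor, roof and lateral wall, and spiral ganglion neurons). With each library left out 1 to 2 passed. The prosensory odds ratio was 0.888 with 100000 peaks, 0.802 with all peaks and 0 with full lists (adjusted p = 0.919, 0.794 and 1), which shows a lost call and no opposite one, and the 0 rests on 165 wildtype-only regions in all. The 1 list that passed near Sox4 sites became 0 lists with sites in all 3 replicates, 10000 peaks or Cdkn1b left out, 2 lists with genes within 10 kb or the further list, 3 lists with all Sox4 peaks, and 0 to 2 lists with each replicate left out (0 without replicate 1 or 3, 2 without replicate 2, supporting cell and epithelium).

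In single cells, thinning to 1000 UMIs gave by construction fewer rows (596 and 531), and without the cell filter the knockout medians were 11965 UMIs and 3018 rows. Rows higher and lower in the knockout library numbered 92 and 276 at 50 CPM, 1147 and 1422 at 1 CPM, 573 and 412 relative to the median, and 511 and 458 with TMM factors.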

Other observations

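In this part, the stricter reading of the tests of gene lists and of Sox4 sites was set only after their values had been seen, and the genes in the next paragraph were chosen after their values were seen.

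Some genes outside the lists were nearest to many genotype-specific regions, and these counts were not tested against gene length. Ctnna2, a catenin gene, and Nrxn3, a gene of a synaptic adhesion protein, were nearest to 11 wildtype-only and 2 knockout-only regions each, and Zbtb20 to 8 and 0. Csmd1, Nav3 and Robo2, an axon guidance receptor gene, were nearest to 7 and 0 each. The lengths of these 6 genes ran from 759 kb for Zbtb20 to 1643 kb for Csmd1, while the shorter Abcc4 (225 kb) was nearest to 8 and 1 regions and Plekha5 (173 kb) to 7 and 2. Lmx1b, a LIM-homeobox gene of 80.2 kb, and Btbd9 (367 kb) were nearest to 0 wildtype-only and 7 knockout-only regions each, and Ntm (969 kb) to 2 and 8. At Isl1, a region open in all 5 libraries ranked 1812, 1375 and 900 in wildtype and 23673 and 24488 in knockout. A peak inside Sox11 (chromosome 12, 27338768 to 27339745 in knockout replicate 1) was found at rank 43151 and 52073 in the knockout lists and in no wildtype list. Peaks at the Sox4 and Sox11 genes were present in all 5 ATAC libraries, and they do not test whether the genes were deleted.

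Wildtype-only regions had a mean of 7.04 coding genes within 500 kb, against 15.9 for knockout-only regions. A candidate explanation is depth: within a genotype, regions found only in the library with the lower -log10 p at rank 50000 had fewer genes than those found only in the other. The difference was -5.98, -7.03 and -2.17 in the wildtype pairs and -2.25 in the knockout pair, against -4.40 to -8.58 between genotypes, so wildtype replicates 1 and 3 differed by more than the closest libraries of different genotype. Base composition of the libraries cannot be told apart from genotype for the difference of -8.89, because no sequence was used and no GC content was known. A biological difference between genotypes stays open and untested.

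Prosensory and medial floor genes together were nearest to 42 wildtype-only and 19 knockout-only regions over 44 genes (odds ratio 3.25, 95% interval 1.89 to 5.60). In strata of gene density the odds ratio was 2.50 (1.33 to 4.68). Random gene lists matched on regions per gene had a mean of 26.4 wildtype-only regions. A fraction of 0.0011 of them had at least the observed share of wildtype-only among their genotype-specific regions (one-sided). Both values lie beyond the bounds set beforehand against gene density and against a few genes with many regions, although the second bound named the count and not the share. These bounds were not used, because these 2 lists were picked from 18 by their own counts, and neither passes over all 18 under either correction (lowest adjusted p = 0.563 and 0.335). Both explanations therefore cannot be told apart from a difference at these genes, which stays a hypothesis.

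Sox4 sites fell in wildtype-only regions more often than in knockout-only regions. A possible explanation is that Sox4 signal appears wherever chromatin is open in wildtype cells, from which the CUT&RUN was made. At equal wildtype rank and nearness to gene ends, wildtype-only regions held sites more often than shared ones (odds ratio 1.46, 1.08 to 1.96), which meets the bound set beforehand against that explanation. In 7 other sets of sites the odds ratio was also above 1 (1.17 to 1.90), with an interval above 1 in 2, sites in all 3 replicates (1.90, 1.11 to 3.28) and without replicate 1 (1.67, 1.15 to 2.42), and an interval covering 1 in 5, among them those without replicate 2 (1.46, 0.934 to 2.28) and 3 (1.51, 0.975 to 2.35), which left 24 and 25 wildtype-only regions with a site. Apart from the further list of replicate 1, these sets reuse the same 3 Sox4 replicates, so they are not separate support. With the full lists of the other genotype searched, 0 of 165 wildtype-only and 8 of 441 knockout-only regions held a site. The odds ratios at equal rank count against the explanation, but the bound was not used, because equal rank in ATAC of unsorted tissue need not be equal openness in the sorted cells. The explanation thus cannot be told apart from a Sox4 preference for wildtype-only regions.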
